A study of Homo sapiens with 18 samples.

How the data were processed

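RNA was measured by sequencing in 18 libraries of THP-1, an established human monocytic leukaemia line that takes on macrophage-like features after treatment with phorbol ester (PMA). Per the labels' protocols, the cells were transduced with 1 of 3 retroviral vectors that also carry GFP: an empty vector (IRES), a vector for the MYC-tagged intracellular domain of NOTCH1 (NIC1), which is the active form of the receptor, or a vector for a dominant-negative Mastermind-like protein (DNMAML), which occupies the Notch transcription complex without activating it. GFP-positive cells were sorted, treated with PMA at 5 ng/ml for 48 h and then left unstimulated or kept with 20 ng/ml of IL-4 for 3 h. RNA was isolated on columns and went into TruSeq RNA libraries, per the labels' protocols. The 6 groups of 3 libraries came from experiments numbered 1, 2 and 3, and each number occurs once in each group.

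Each deposited file holds whole-number counts of reads per gene, not normalized, made by the authors. Per the submitters' processing notes, the tools were FastQC, Trimmomatic, HISAT2, HTSeq and DESeq2 with the genome build GRCh38.p12. Their versions, their settings, the annotation release and the strand setting of the counting are not given in the sources used here. Reads from an antisense or overlapping gene therefore may have been counted together with those of a named gene, and close paralogs can share reads that were not assigned. Each file lists 58051 genes by Ensembl identifier, of which 56948 had a symbol in the name table used here and 57447 were found in GENCODE release 29, from which the coordinates (GRCh38, 1-based) were taken.

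Entries that name no gene were kept out of library sizes and tests. They held between 23.8% and 30.9% of the reads in each library, made up of reads in no annotated gene (3.79% to 6.72%), ambiguous reads (2.38% to 2.56%), reads not aligned (1.20% to 2.69%) and reads with more than 1 alignment (15.6% to 19.2%). Counts assigned to genes came to between 12410668 and 15099788 per library. Libraries of one group differed by far more than counting noise, with chi-square divided by degrees of freedom between 5.45 and 48.5 over pairs, so no library was treated as a duplicate of another.

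Genes were kept by edgeR's filterByExpr over the 6 groups, which left 15037 genes. Library sizes were scaled by the trimmed mean of M values (TMM), and levels are given in CPM on that scale, with the SD over 3 libraries. The main test was edgeR's quasi-likelihood F test (glmQLFit with robust dispersion, glmQLFTest) in a single model of 6 group means over all 18 libraries, with Benjamini-Hochberg adjustment over the 15037 genes in each contrast and a threshold of 0.05 on the adjusted p. Log2 fold changes are given with a standard error derived from the F statistic. The 11 contrasts were the IL-4 response in each construct, NIC1 and DNMAML against IRES and against each other without and with IL-4, and the difference in IL-4 response of NIC1 and of DNMAML from IRES. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and version 1.17.8 of the data.table package, with Python 3.11.15 and matplotlib 3.10.9 for figures.

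The experiment numbers paired the libraries. The deviations of log2 CPM (prior count 2) from the group means correlated between libraries of the same number in all 45 pairs, with Pearson r across genes between 0.206 and 0.759 and a median of 0.466, against a median of -0.395 over 90 pairs of different numbers. All 18 libraries lay closest to a library of their own number. A model with the experiment number as a block was fitted beside the main one, and its value is given as the blocked value wherever it changed the call of a gene or list described for a comparison or moved a count by more than 1.5 times. Log2 changes and standard errors beside a blocked adjusted p are those of the main model, so their ratio does not match that p. Nothing in the labels says whether libraries of one number came from separate transductions or cultures, so p-values measure the spread between these libraries, which may be technical in part. Both models treat the libraries of one construct and number without and with IL-4 as independent. If these came from one culture, blocked p-values between constructs may be too small.

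Before the data were examined, 21 gene lists were fixed: Notch targets, Notch pathway components, IL-4 and STAT6 response genes, IL-4 receptor signalling components, NF-kappaB and inflammatory cytokine genes, interferon-stimulated genes, macrophage identity genes, MHC class II genes, cell cycle genes, cholesterol synthesis genes, cholesterol efflux and fatty acid genes, glycolysis genes, unfolded protein response genes, immediate early genes, apoptosis regulators, myeloid progenitor markers, mitochondrially encoded genes, and markers of T cells, B cells, fibroblasts and epithelia, and erythroid cells and megakaryocytes. Members past the threshold over all genes and members past it when adjusted over the list alone were counted, and limma's camera (preset correlation 0.01) tested each list of at least 5 tested members against all other genes, adjusted over the lists of a contrast. Camera with an estimated correlation and limma's fry were run beside it.

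The genes named were also set by a rule fixed before the data were examined: NOTCH1, MAML1, HES1, HEY1 and NRARP between constructs, 12 known IL-4 response genes in every contrast with IL-4, the 6 genes with the highest and the 6 with the lowest log2 fold change among called genes with a symbol, at least 2 CPM in a group and no overlap between the libraries compared, and up to 4 members with the smallest adjusted p in each list with a called member. Of the 12 IL-4 response genes, CCL17 (16 counts over all libraries), MRC1 (5 counts) and IRF4 (53 counts) did not pass the filter and were not tested. A gene outside this rule is said to have been chosen after its values were seen, and some genes within it are not reported here.

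Alternatives planned before the data were examined were DESeq2 size factors in the same model, the DESeq2 Wald test, no filter on low counts, a stricter filter (5 CPM in 3 libraries), only the libraries of the groups compared, the block, a 2-fold minimum and each library left out in turn. Alternatives chosen after the data were seen were the omission of the 2 libraries with the most genes detected, the same with the block or an estimated correlation, or both, camera with both the block and an estimated correlation, and a block for each construct and number in the IL-4 contrasts. The test was tried on simulated counts with the means, dispersions and library sizes of these libraries and 200 changed genes. For the IL-4 response in IRES cells, it called 36% of 50 genes changed by 1.5-fold, 60% at 2-fold, 80% at 3-fold and 88% at 5-fold, and 72%, 84%, 92% and 90% with the block, and 5.04% and 3.98% of its calls were false. For DNMAML against IRES without IL-4 it called 32%, 60%, 80% and 82%, and 62%, 78%, 94% and 92% with the block, with 6.62% and 2.40% false. For NIC1 against IRES without IL-4 it called 46%, 68%, 80% and 90%, and 58%, 80%, 84% and 98% with the block, with 6.58% and 6.98% false. For the difference in IL-4 response between NIC1 and DNMAML, the model with a block for each construct and number called 64%, 70%, 88% and 94%, and 9.71% of its calls were false. That comparison was itself added after the data were seen. In the simulations of the test without the block, libraries of one number shared no deviation, unlike the measured libraries. The shares for that test therefore apply to unpaired libraries, and it may behave otherwise on the measured ones.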

Results

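Gene expression was measured in 18 RNA-seq libraries of PMA-treated THP-1 cells carrying an empty vector (IRES), the NOTCH1 intracellular domain (NIC1) or dominant-negative Mastermind-like (DNMAML), each without IL-4 and after 3 h of IL-4, with 3 libraries in each of the 6 groups. The series set out to follow raised and lowered Notch signalling in IL-4-stimulated cells. Between 12410668 and 15099788 reads per library were counted in genes, and 15037 genes were tested. The first principal component, with 35.0% of the variance, set the libraries of experiment 2 apart from those of experiments 1 and 3. Within each experiment and condition it also ordered the constructs, with NIC1 highest, then IRES, then DNMAML. The second component (21.0%) followed IL-4 and the third (11.5%) parted NIC1 from DNMAML. Libraries stood apart in the number of genes with at least 1 count in 2 cases: 23179 in IRES unstimulated replicate 3 and 25322 in DNMAML with IL-4 replicate 3, against 21067 to 21557 in the other 16.

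**Figure D1:**
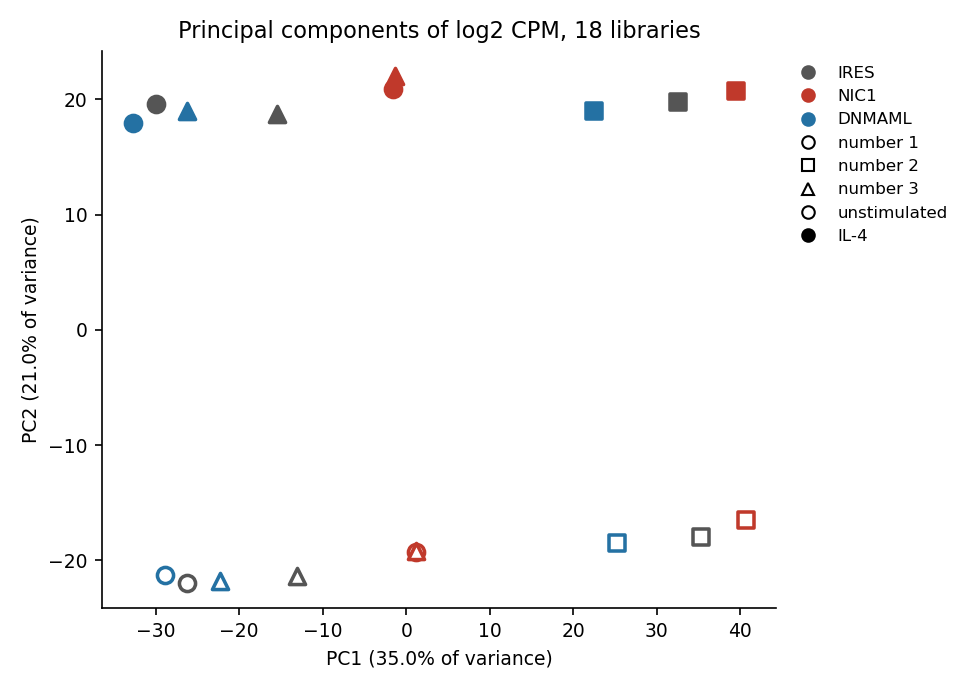
Principal components of log2 CPM in the 18 libraries, with colour for the construct, the marker shape for the experiment number and filled markers for IL-4; each point is 1 library. Component 1 (35.0% of the variance) holds the libraries of experiment 2 on one side, and component 2 (21.0%) parts libraries with IL-4 from those without.

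To see whether the vectors were reflected in the counts, the genes behind them were examined first. NOTCH1 (9:136494433 to 136545786, minus strand), the receptor whose intracellular domain NIC1 encodes, was measured at 188 ± 40.5 CPM (SD, n = 3) in IRES cells, 287 ± 55.3 in NIC1 cells and 152 ± 23.4 in DNMAML cells without IL-4. With IL-4 it was measured at 231 ± 38.9, 395 ± 49.3 and 187 ± 43.5 CPM. MAML1 (5:179732850 to 179777286, plus strand), a co-activator of the Notch complex, was measured at 88.8 ± 9.30 CPM in IRES cells, 81.9 ± 5.81 in NIC1 cells and 131 ± 8.07 in DNMAML cells without IL-4, and with IL-4 the values were 84.2 ± 5.25, 86.4 ± 5.56 and 114 ± 11.6 CPM. Counts of both genes include any reads from the vectors that align to them. Against IRES, the log2 change of NOTCH1 in NIC1 cells was 0.61 ± 0.195 without IL-4 (edgeR adjusted p = 0.377, blocked adjusted p = 1.06e-06) and 0.78 ± 0.195 with IL-4 (adjusted p = 0.184, blocked 4.58e-08). The log2 change of MAML1 in DNMAML cells was 0.56 ± 0.092 without IL-4 (adjusted p = 0.258, blocked 0.0025) and 0.44 ± 0.092 with IL-4 (adjusted p = 1, blocked 0.0246). Between NIC1 and DNMAML cells, NOTCH1 was higher in NIC1 by 0.92 ± 0.196 without IL-4 (adjusted p = 0.0282) and by 1.08 ± 0.196 with IL-4 (adjusted p = 0.0113), and MAML1 was lower in NIC1, at -0.68 ± 0.092 (adjusted p = 0.00127) and -0.40 ± 0.092 (adjusted p = 0.0385). The NOTCH1 call was lost without NIC1 replicate 2, DNMAML replicate 1 or DNMAML replicate 3, reaching an adjusted p of 0.152 without IL-4 and 0.0782 with IL-4. The MAML1 call held in every leave-out without IL-4 and in 1 of 6 with IL-4, where the adjusted p reached 0.209.

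**Figure D2:**
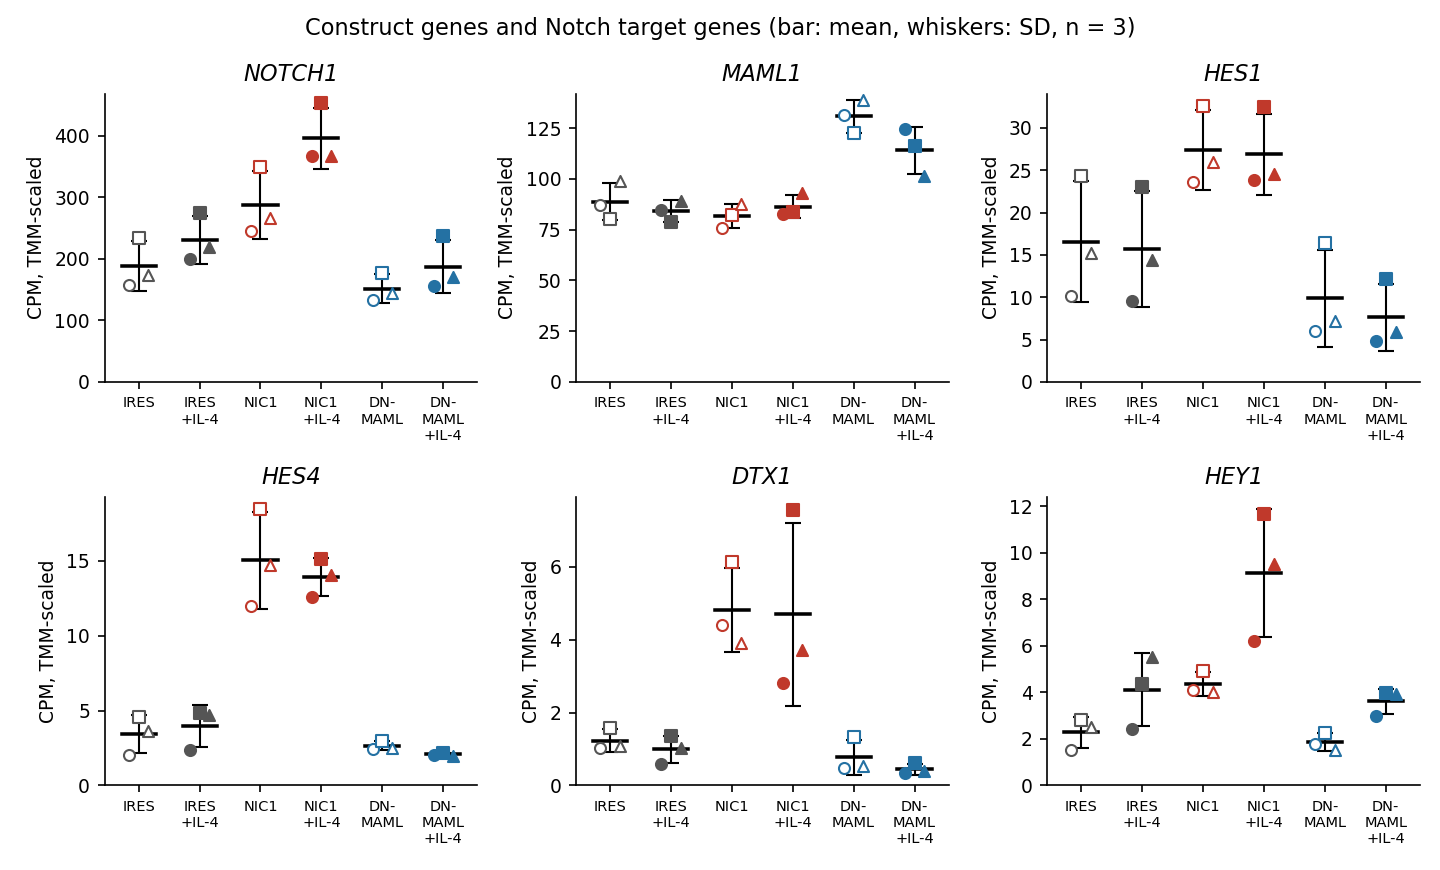
Level of Notch genes in CPM, TMM-scaled, on axes that start at 0, for the 6 groups; points are libraries (circle, square and triangle for experiments 1, 2 and 3, filled with IL-4), and horizontal lines are means with whiskers for the SD of 3 libraries. NOTCH1 had means of 287 CPM in NIC1 cells and 188 CPM in IRES cells without IL-4, and HES4 had means of 15.1 and 3.41 CPM.

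IL-4 signals through STAT6 and is used to drive macrophages towards an alternatively activated state, and its effect was first measured in cells with the empty vector. CISH and SOCS1, which encode feedback inhibitors of cytokine signalling, rose. CISH (3:50606490 to 50611831) went from 1.57 ± 0.434 to 114 ± 12.9 CPM (log2 change 6.16 ± 0.185, adjusted p = 4.79e-12). SOCS1 (16:11254405 to 11256200) went from 0.991 to 52.6 ± 11.6 CPM (5.72 ± 0.273, adjusted p = 2.33e-09). The lipoxygenase gene ALOX15 rose by 3.31 ± 0.232 (adjusted p = 2.74e-07). The transglutaminase gene TGM2 rose by 1.84 ± 0.295, the nuclear receptor gene PPARG by 1.37 ± 0.267 and the interleukin 1 receptor antagonist gene IL1RN by 1.71 ± 0.177. Among called genes with a symbol, at least 2 CPM in a group and no overlap between the libraries compared, the serpin SERPINB4 (6.40 ± 0.577), the chemokine CCL8 (6.08 ± 1.04), PPP1R14A (5.26 ± 0.43) and the C-type lectin CLEC4A (4.97 ± 0.392) had the other highest changes. Genes that fell included the semaphorin SEMA6D (-2.07 ± 0.384), ZNF608 (-2.05 ± 0.344), the cytokine gene TGFB2 (-1.91 ± 0.252), SESN1 (-1.68 ± 0.147) and the transcription factor genes KLF4 (-1.04 ± 0.206) and FOS, whose mean went from 79.7 to 30.5 CPM. In all, 441 genes were called, 304 higher and 137 lower (1360 blocked, 732 higher and 628 lower).

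Among 27 tested IL-4 and STAT6 response genes, 10 rose and 1 fell (13 and 1 adjusted over the list alone). The list was higher as a set (camera adjusted p = 5.39e-18; adjusted p = 6.2e-06 with an estimated correlation). Of 27 IL-4 receptor signalling components, 6 rose (9 rose and 1 fell adjusted over the list alone), among them STAT5A (0.73 ± 0.109) and the phosphatase gene PTPN1 (0.49 ± 0.067) beside CISH and SOCS1 (camera adjusted p = 9.04e-06; adjusted p = 0.0169 with an estimated correlation). The low-affinity Fc receptor genes FCGR2A (2.19 ± 0.33) and FCGR2B (2.28 ± 0.29) and the myeloid factor CEBPA (1.07 ± 0.209) rose within the macrophage identity list while TLR4 (-0.92 ± 0.156) fell, and that list as a set was not called. NFKB1 rose by 0.47 ± 0.07, and TNFAIP3, which restrains NF-kappaB, fell (-0.77 ± 0.135). CDKN1A (1.21 ± 0.107), FAS (1.12 ± 0.18), ATF3 (1.15 ± 0.178) and the haematopoietic factor TAL1 (2.70 ± 0.217) also rose, and the lipid droplet gene PLIN2 fell (-1.09 ± 0.108). The lectin gene CD209 rose by 1.67 ± 0.404 (adjusted p = 0.0313), a call lost without IRES unstimulated replicates 2 or 3 or IRES with IL-4 replicates 1 or 3, where its adjusted p reached 0.168. The IgE receptor gene FCER2 rested on 2 counts without and 21 with IL-4 and missed the threshold (3.11 ± 0.852, adjusted p = 0.0679, blocked 0.0185), as did the chemokine gene CCL22 (0.25 ± 0.203, adjusted p = 0.901). Of 37 named and called genes in this response, 34 kept their call in every leave-out. With the 2 libraries with the most genes detected left out, chosen after the data were seen, 286 genes were called, and 191 were called when only the libraries of these 2 groups were fitted.

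The same response was then measured in NIC1 and DNMAML cells. In NIC1 cells, CISH rose from 2.25 to 110 ± 1.19 CPM (log2 change 5.60 ± 0.178, adjusted p = 1.12e-11), SOCS1 by 5.17 ± 0.262, ALOX15 by 3.58 ± 0.237, PPARG by 1.64 ± 0.267 and FCER2 by 3.25 ± 0.546 (adjusted p = 0.00208), and KLF4 fell by 1.32 ± 0.202. In DNMAML cells, CISH rose from 2.22 to 124 ± 23.1 CPM (5.79 ± 0.177, adjusted p = 6.3e-12), SOCS1 by 5.37 ± 0.266, ALOX15 by 3.00 ± 0.232 and TGM2 by 2.14 ± 0.298. SERPINB4, PPP1R14A and CLEC4A were again among the 6 highest changes within these limits in both, with SERPINB4 at 9.40 ± 0.763 in NIC1 and 8.78 ± 0.784 in DNMAML cells, joined by ANKRD22 (4.74 ± 0.886) in NIC1 cells and the hyaluronan synthase gene HAS3 (4.39 ± 0.311) in DNMAML cells. ZNF608 and SESN1 were again among the 6 lowest in both. The ZNF608 call was lost in 3 of 6 leave-outs in NIC1 cells (adjusted p up to 0.0617) and in 2 of 6 in DNMAML cells (up to 0.0639). Of 40 named and called genes in each response, 31 kept their call in every leave-out in NIC1 and 29 in DNMAML cells.

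In NIC1 cells 458 genes were called, 338 higher and 120 lower (1323 blocked, 772 and 551), and in DNMAML cells 493, with 324 higher and 169 lower (1496 blocked, 753 and 743). In both, 11 of the 27 IL-4 and STAT6 response genes rose and 1 fell (13 and 1 adjusted over the list alone), with camera adjusted p = 3.7e-16 in NIC1 and 8.76e-16 in DNMAML cells (adjusted p = 1.12e-05 and 1.27e-05 with an estimated correlation). The IL-4 receptor signalling list was called in both, with 7 members higher and 1 lower in NIC1 cells (8 and 1 adjusted over the list alone; camera adjusted p = 6.13e-06, 0.0151 with an estimated correlation) and 6 higher and 1 lower in DNMAML cells (9 and 1 adjusted over the list alone; adjusted p = 3.38e-05, 0.025 with an estimated correlation). Progenitor factor MYB fell by 1.19 ± 0.256 in NIC1 cells (adjusted p = 0.014), a call lost in 3 of 6 leave-outs. In DNMAML cells the Notch pathway list (0 of 38 members called, 0 adjusted over the list alone) and the T cell list (0 of 8, 0 adjusted over the list alone) were lower as sets, each with a camera adjusted p of 0.039 (adjusted p = 0.0677 and 0.0857 with an estimated correlation). The Notch pathway call was lost without the 2 libraries with the most genes detected (adjusted p = 0.136). PPARG rose by 1.03 ± 0.266 in DNMAML cells with an adjusted p of 0.0464, and this call was lost in each of the 6 leave-outs. The DNMAML count fell to 301 without DNMAML unstimulated replicate 3 and to 327 without DNMAML with IL-4 replicate 3, and to 296 without both libraries with the most genes detected, of which the second is in this comparison.

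**Figure D3:**
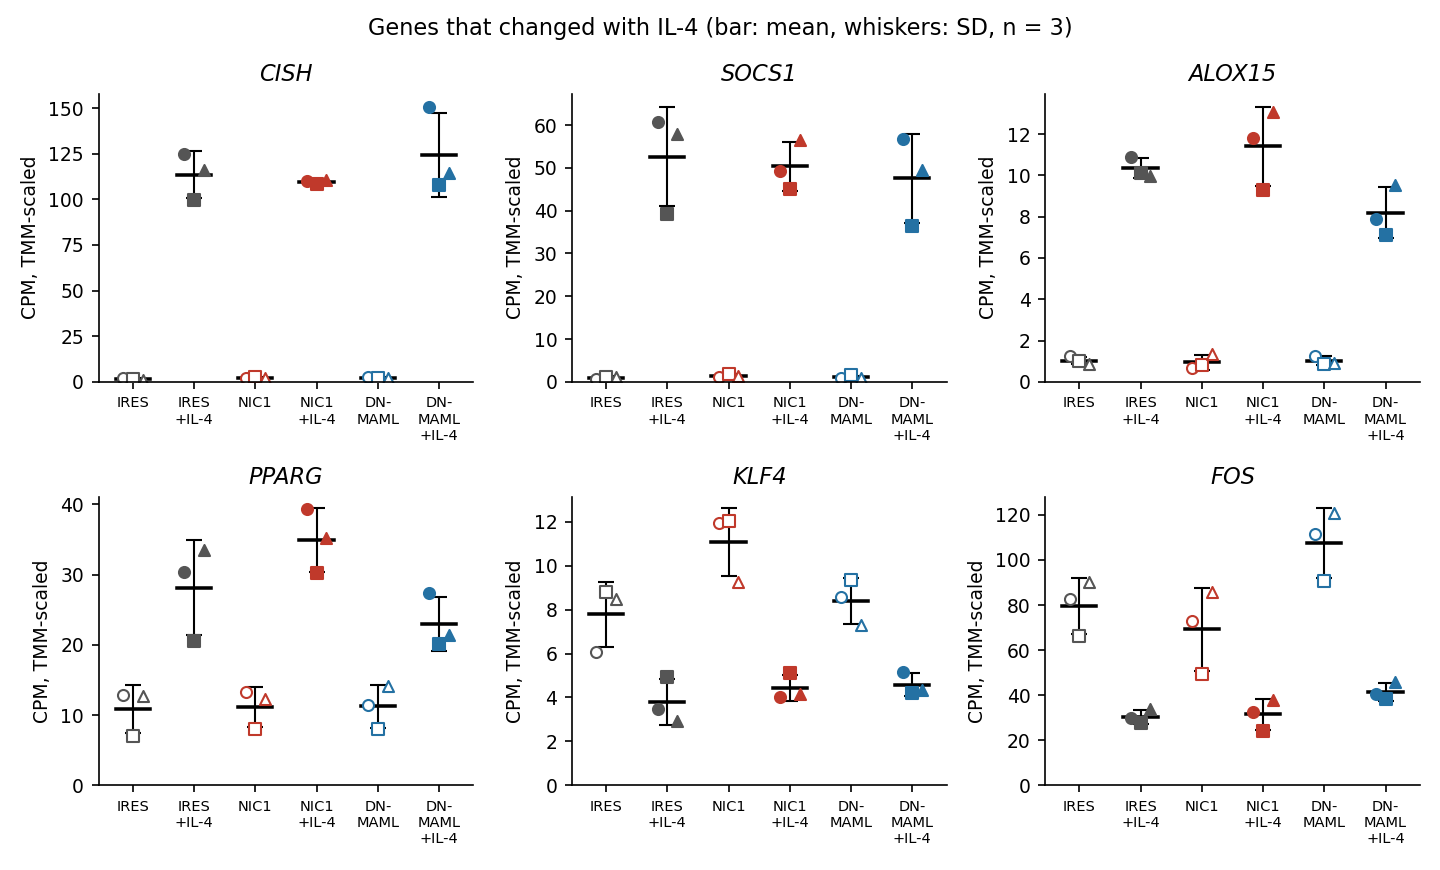
Level of IL-4 response genes in CPM, TMM-scaled, on axes that start at 0, for the 6 groups; points are libraries (circle, square and triangle for experiments 1, 2 and 3, filled with IL-4), and horizontal lines are means with whiskers for the SD of 3 libraries. CISH had a mean of 1.57 CPM in IRES cells without IL-4 and of 114, 110 and 124 CPM in IRES, NIC1 and DNMAML cells with IL-4.

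The 3 IL-4 responses named many of the same genes. Of 640 genes called in at least 1 construct, 318 were called in the same direction in all 3, 235 higher and 83 lower (899 of 1992 blocked). IRES and NIC1 cells shared 258 higher and 95 lower genes against 6.83 and 1.09 for independent lists, IRES and DNMAML cells 268 and 107 (6.55 and 1.54), and NIC1 and DNMAML cells 250 and 92 (7.28 and 1.35), with no gene called in opposite directions. Across the tested genes, which are not independent replicates, log2 changes correlated at r = 0.779, 0.787 and 0.747 for these pairs, which share no library but share experiment numbers. The difference between responses was tested directly. CISH rose by 0.56 ± 0.265 less in NIC1 than in IRES cells (adjusted p = 1), and the differences of SOCS1 (-0.55 ± 0.408), PPARG (0.27 ± 0.373) and TGM2 (-0.50 ± 0.405) had adjusted p = 1 as well. In DNMAML cells the differences from IRES were -0.37 ± 0.262 for CISH, -0.34 ± 0.374 for PPARG and 0.30 ± 0.405 for TGM2, each with adjusted p = 1. No gene was called by edgeR for a difference in IL-4 response, with 121 genes at an unadjusted p under 0.05 for NIC1 and 98 for DNMAML. DESeq2 called none either, with 73 and 52. All these counts lie below the 752 expected by chance, as do 366 and 237 with the experiment number as a block. The lack of calls therefore does not show equal responses. With a block for each construct and number, chosen after the data were seen, edgeR called 0 and 0, with 811 and 474 at an unadjusted p under 0.05. With all libraries and no block, no list was called in either difference, and the lowest camera adjusted p was 0.055 for Notch pathway components in NIC1 cells (28 of 38 members above 0, median difference 0.0602; adjusted p = 0.0999 with an estimated correlation; blocked adjusted p = 0.00302; adjusted p = 0.408 with both). Without the 2 libraries with the most genes detected, lists were called in both. For NIC1, interferon-stimulated genes were lower (adjusted p = 0.00934; adjusted p = 0.987 with an estimated correlation). For DNMAML, interferon-stimulated genes (adjusted p = 3.32e-06) and unfolded protein response genes (0.000599) were lower and mitochondrially encoded genes higher (0.00144), each with adjusted p = 0.7 with an estimated correlation. With the block in addition, unfolded protein response genes were lower and mitochondrially encoded genes higher for NIC1 (blocked 0.045 for both; adjusted p = 0.989 for both with the block and an estimated correlation). For DNMAML, cell cycle genes were then higher and the T cell list lower (blocked 0.0309 for both; adjusted p = 0.807 and 0.485 with the block and an estimated correlation).

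The vector meant to raise Notch activity was examined by comparing NIC1 with IRES cells. Of 16 tested Notch targets, HES4 was called without IL-4 and HES4 and DTX1 with it. HES4 (1:998962 to 1000172), a transcriptional repressor of the HES family, rose from 3.41 ± 1.27 to 15.1 ± 3.24 CPM without IL-4 (log2 change 2.14 ± 0.271, adjusted p = 0.00593). With IL-4 it rose from 3.97 ± 1.39 to 13.9 ± 1.28 CPM (1.81 ± 0.267, adjusted p = 0.0141). DTX1 (12:113056709 to 113098028), which encodes a ubiquitin ligase of the pathway, rose with IL-4 (2.25 ± 0.423, adjusted p = 0.0432). Without IL-4 it missed the threshold (1.96 ± 0.413, adjusted p = 0.0696, blocked 2.17e-05). The T cell receptor component CD3G (11:118344344 to 118355161) rose from 0.0962 to 3.54 ± 1.08 CPM without IL-4 (5.04 ± 0.624, adjusted p = 0.00593) and by 5.75 ± 0.7 with IL-4 (adjusted p = 0.00399). In IRES cells CD3G rested on 4 counts without and 2 with IL-4, so the size of its change is uncertain. The lipid-presenting molecule CD1C (1:158289786 to 158293630) rose from 0.569 to 3.67 ± 1.01 CPM (2.67 ± 0.401, adjusted p = 0.0183) and by 2.45 ± 0.372 with IL-4 (adjusted p = 0.0141). The matrix genes MMP2, a gelatinase, and SPARC fell in both conditions. MMP2 went from 140 ± 19.9 to 76.6 CPM without IL-4 (-0.87 ± 0.145, adjusted p = 0.026) and fell by 0.86 ± 0.145 with IL-4 (adjusted p = 0.0281). SPARC fell by 0.53 ± 0.09 and by 0.51 ± 0.091.

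Without IL-4, 35 genes were called, 28 higher and 7 lower (808 blocked, 517 and 291). With IL-4, 30 were called, 26 higher and 4 lower (818 blocked, 567 and 251). PPP1R3A (2.73 ± 0.493 and 2.68 ± 0.492), the polymeric immunoglobulin receptor gene PIGR (2.20 ± 0.341 and 2.02 ± 0.357) and the granule protease gene PRTN3 (0.68 ± 0.128 and 0.72 ± 0.128) rose in both. EEF1A2 (-0.68 ± 0.12 and -0.73 ± 0.12) and ADCY6 (-0.70 ± 0.118 and -0.62 ± 0.119) fell in both. ARNT2 (1.90 ± 0.31) and the survival gene BCL2A1 (0.88 ± 0.146) rose and MANSC1 (-0.79 ± 0.148) and KCNH2 (-0.68 ± 0.132) fell without IL-4. Both conditions shared 24 calls in the same direction, 20 higher and 4 lower, against 0.0484 and 0.00186 for independent lists. Across genes, log2 changes correlated at r = 0.609 between the conditions. The conditions share no library, but they share experiment numbers. Libraries of one construct and number were closer to each other than other libraries of one number. A difference between cultures could therefore recur in both conditions, and the values for independent lists do not allow for it. The classical target HES1 was called with the block alone, at 0.72 ± 0.426 without IL-4 (blocked adjusted p = 0.0112) and 0.78 ± 0.426 with it (blocked 0.00632). So was HEY1, at 0.93 ± 0.313 (blocked 0.0123) and 1.16 ± 0.289 (blocked 0.000373). CD3D, at 2.61 ± 0.535 (blocked 0.000108) and 2.48 ± 0.541 (blocked 0.000228), was called in the same way. NRARP was called in neither fit (0.58 ± 0.252 and 0.25 ± 0.253). Among IL-4 response genes with IL-4, the differences of CISH (-0.05 ± 0.131), SOCS1 (-0.07 ± 0.191), ALOX15 (0.14 ± 0.188), PPARG (0.31 ± 0.254) and KLF4 (0.23 ± 0.21) had adjusted p = 1. FCER2, with 21 counts in IRES and 87 in NIC1 cells, was called with the block alone (2.04 ± 0.463, adjusted p = 0.108, blocked 0.00232).

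As sets, 6 lists were called in both conditions. Notch targets were higher, with 1 of 16 members called without IL-4 and 2 with it (3 and 3 adjusted over the list alone). Their camera adjusted p was 8.1e-06 and 2.34e-06 (adjusted p = 0.323 and 0.256 with an estimated correlation). With both the block and an estimated correlation, Notch targets were called in both conditions. Immediate early genes, which answer stimuli quickly, were higher with 21 and 22 of 23 members above 0 and medians of 0.436 and 0.372. None passed singly (6 and 0 adjusted over the list alone, 13 and 10 blocked). Their camera adjusted p was 3.59e-09 and 2.92e-09 (adjusted p = 0.0351 and 0.034 with an estimated correlation). IL-4 and STAT6 response genes were higher, with CD1C called in both (2 and 6 adjusted over the list alone). Their camera adjusted p was 8.1e-06 and 0.000278 (adjusted p = 0.00286 and 0.015 with an estimated correlation). With both the block and an estimated correlation, they were called without IL-4 alone. CD1C itself differed more between constructs than with IL-4. It was at 0.569 CPM without and 0.828 with IL-4 in IRES cells, and at 3.67 and 4.54 in NIC1 cells. NF-kappaB and inflammatory cytokine genes were higher with 0 of 30 members called (0 and 2 adjusted over the list alone, 6 and 9 blocked). The test gave adjusted p = 6.48e-05 and 7.6e-05 (adjusted p = 0.432 and 0.359 with an estimated correlation). Cell cycle genes were lower with 0 of 35 called (0 and 0 adjusted over the list alone). Here the test gave adjusted p = 0.00286 and 0.00015 (adjusted p = 0.834 and 0.671 with an estimated correlation). The T cell list was higher with CD3G alone called (3 and 2 adjusted over the list alone). It had adjusted p = 0.00448 and 0.0236 (adjusted p = 0.04 and 0.108 with an estimated correlation), and the call with IL-4 was lost with the block (0.0695).

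In the fit without the block, the calls of single genes in NIC1 against IRES depended on single libraries. The leave-outs were not run with the block. Without IL-4 the count was 3, 26 and 0 without IRES replicates 1, 2 and 3, and 3, 8 and 9 without NIC1 replicates 1, 2 and 3. With IL-4 it was 0, 9 and 7 without IRES replicates 1, 2 and 3, and 9, 18 and 11 without NIC1 replicates 1, 2 and 3. CD3G and HES4 lost their calls in a single leave-out per condition. It was IRES replicate 3 without IL-4 (adjusted p = 0.0541 for both) and IRES replicate 1 with IL-4 (0.0539 and 0.0579). The other named genes lost theirs in 3 or more of the 6, where the adjusted p reached 0.322 for MANSC1 without IL-4 and 0.326 for DTX1 with it. With the 2 libraries with the most genes detected left out, edgeR called 0 genes without IL-4 and 11 with it. Without IL-4, 810 genes had an unadjusted p under 0.05. With the block in addition, 562 genes were called without IL-4, among them all 35 called in the main fit. With only the 2 groups compared in the fit, edgeR called 0 in either condition, with 729 and 782 at an unadjusted p under 0.05. The DESeq2 Wald test called 91 and 108.

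The vector meant to lower Notch activity was examined by comparing DNMAML with IRES cells. No gene was called by edgeR without IL-4, where 371 had an unadjusted p under 0.05, or with IL-4, where 357 did. By chance 752 would be expected. The test without the block thus gave too few small p-values here, and a count of 0 does not show an absence of change. With the block, 1231 and 1166 genes had an unadjusted p under 0.05. DESeq2 called MAML1 (0.56 ± 0.104) and the transcription factor gene MAF (-1.23 ± 0.258) without IL-4 and the phosphatase gene ACP5 with it. MAF and ACP5 lie outside the naming rule and were chosen after their values were seen. With the block, 22 genes were called without IL-4, 10 higher and 12 lower, and 14 with IL-4, 6 higher and 8 lower. With the 2 libraries with the most genes detected left out as well, 1 of which is in each comparison, 2 and 6 were called, MAML1 among them in both conditions and NOTCH1 in neither. With all libraries, NOTCH1 was called with the block in both conditions (-0.31 ± 0.195, blocked adjusted p = 0.0315, and -0.30 ± 0.195, blocked 0.0253), as was MAML1. HES1 was measured at 9.89 ± 5.72 CPM in DNMAML and 16.6 ± 7.16 in IRES cells without IL-4, and at 7.61 ± 3.92 and 15.7 ± 6.83 with it. Its log2 changes of -0.75 ± 0.44 and -1.05 ± 0.448 missed the threshold in both fits (blocked adjusted p = 0.134 and 0.0516). HEY1 (-0.29 ± 0.333 and -0.18 ± 0.299) and NRARP (0.05 ± 0.255 and -0.02 ± 0.255) had adjusted p = 1. With IL-4, the changes of CISH (0.13 ± 0.13), SOCS1 (-0.15 ± 0.191), ALOX15 (-0.33 ± 0.19), PPARG (-0.29 ± 0.256), TGM2 (-0.16 ± 0.285), KLF4 (0.28 ± 0.21) and CD209 (-0.12 ± 0.367) had adjusted p = 1.

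Lists were called as sets in DNMAML against IRES with 0 members past the threshold over all genes. Cell cycle genes were lower in both conditions, with 1 and 0 of 35 members above 0 (0 and 0 adjusted over the list alone). Their camera adjusted p was 8.92e-06 and 4.13e-06 (adjusted p = 0.938 and 0.856 with an estimated correlation). Myeloid progenitor markers were lower (0 and 1 adjusted over the list alone), with adjusted p = 0.00538 and 0.0302 (adjusted p = 0.0856 and 0.217 with an estimated correlation). The call with IL-4 was lost with the block (0.0548). NF-kappaB and inflammatory cytokine genes were higher without IL-4 (0 adjusted over the list alone), with adjusted p = 0.0139 (adjusted p = 0.938 with an estimated correlation). With IL-4 they were higher in the blocked test alone (0.063, blocked 0.0159; adjusted p = 0.552 with the block and an estimated correlation). MHC class II genes were lower with IL-4, with 1 of 7 members above 0 (0 adjusted over the list alone) and adjusted p = 0.0344 (adjusted p = 0.856 with an estimated correlation). In the blocked test alone, Notch targets were lower without IL-4 (camera adjusted p = 0.182, blocked 0.0474) and with it (0.063, blocked 0.0147). Both calls were lost with the block and an estimated correlation (adjusted p = 0.513 and 0.371). Interferon-stimulated genes were higher in the blocked test without (0.182, blocked 6.71e-06) and with IL-4 (0.244, blocked 0.00165), and both calls were lost in the same way (adjusted p = 0.556 and 0.583). So were those of macrophage identity genes (0.182, blocked 0.00719) and unfolded protein response genes (0.439, blocked 0.0159), higher without IL-4 in the blocked test (adjusted p = 0.464 and 0.556). Mitochondrially encoded genes were lower in it with IL-4 (0.063, blocked 0.00288; adjusted p = 0.552 with the block and an estimated correlation), and DNMAML with IL-4 replicate 3 held 0.665% of its gene counts in them, against 1.32% to 2.98% in the other 17 libraries. Without the 2 libraries with the most genes detected, of which this is 1, these genes were higher in DNMAML with IL-4 (adjusted p = 0.0144, blocked 0.000977; adjusted p = 0.79 with an estimated correlation). Without IL-4, interferon-stimulated genes (adjusted p = 0.000585) and unfolded protein response genes (0.0195) were then called higher without the block as well (adjusted p = 0.708 for both with an estimated correlation). MHC class II genes with IL-4 were called without the block (0.0117) but not with it (blocked 0.0575). The blocked calls of Notch targets (0.139 and 0.0543) and, with IL-4, of interferon-stimulated (0.675) and NF-kappaB genes (0.242) were then lost, as was that of NF-kappaB genes without IL-4 in the test without the block (0.256).

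NIC1 and DNMAML cells, which carry the activating and the blocking vector, were compared directly. HES4 was higher in NIC1 by 2.50 ± 0.278 without and 2.75 ± 0.284 with IL-4 (adjusted p = 0.000327 and 0.000271) and DTX1 by 2.64 ± 0.438 and 3.38 ± 0.472 (adjusted p = 0.00591 and 0.00133). CD3G (5.97 ± 0.692 and 5.28 ± 0.657), CD3D (3.80 ± 0.582 and 3.88 ± 0.602), CD1C (5.14 ± 0.532 and 3.41 ± 0.41) and PPP1R3A (3.84 ± 0.56 and 3.77 ± 0.56) were higher in both conditions. So were the scavenger receptor gene CD36 (1.60 ± 0.317 and 1.66 ± 0.321) and the cytokine genes LTB (2.98 ± 0.559 and 2.56 ± 0.56) and SPP1 (0.88 ± 0.162 and 0.86 ± 0.162). PRTN3 (1.09 ± 0.129 and 1.26 ± 0.13) and the progenitor gene SPINK2 (1.76 ± 0.331 and 1.61 ± 0.344) were higher too. In DNMAML cells CD3G rested on 2 counts without and 3 with IL-4, and CD1C on 4 and 18, so the sizes of their changes are uncertain. MMP2 (-1.26 ± 0.145 and -1.28 ± 0.145), the integrin gene ITGAM (-0.78 ± 0.12 and -0.57 ± 0.119), the keratin gene KRT18 (-1.11 ± 0.209 and -1.13 ± 0.209) and KIF26A (-1.37 ± 0.308 and -1.35 ± 0.283) were lower.

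Without IL-4, 248 genes differed between NIC1 and DNMAML, 156 higher and 92 lower in NIC1 (2082 blocked, 1108 and 974). With IL-4, 216 differed, 162 higher and 54 lower (1893 blocked, 1097 and 796). Of these, 113 higher and 38 lower were shared by both conditions, against 1.68 and 0.33 for independent lists, and log2 changes across genes correlated at r = 0.718. Here too, libraries of one construct and number may not be independent across the conditions, which the values for independent lists do not allow for. Notch targets were higher with 2 of 16 members called without and 3 with IL-4 (5 and 5 adjusted over the list alone). The camera adjusted p was 1.45e-05 and 4.32e-06 (adjusted p = 0.265 and 0.223 with an estimated correlation). With both the block and an estimated correlation, Notch targets were called in both conditions. HEY1 was called with IL-4 (1.33 ± 0.291, adjusted p = 0.0304) and, with the block alone, without it (1.22 ± 0.319, adjusted p = 0.0707, blocked 0.000843). HES1 was called with the block alone in both (1.47 ± 0.439, blocked 2.3e-05, and 1.83 ± 0.447, blocked 3.76e-06). IL-4 and STAT6 response genes were higher with 3 and 2 of 27 called, CD1C and CD1A in both. Adjusted over the list alone, 6 were higher and 3 lower without IL-4 and 5 higher with it. The camera adjusted p was 0.00297 and 0.00136 (adjusted p = 0.0382 and 0.0253 with an estimated correlation). Neither call held with both the block and an estimated correlation. With IL-4, PPARG (0.60 ± 0.256, blocked adjusted p = 0.000909), ALOX15 (0.48 ± 0.19, blocked 0.0252) and FCER2 (1.69 ± 0.446, blocked 0.00314) were called with the block alone. Immediate early genes were higher with 0 and 1 of 23 called. Adjusted over the list alone, 7 were higher and 1 lower without IL-4 and 9 higher with it. The camera adjusted p was 8.36e-06 and 7.9e-07 (adjusted p = 0.093 and 0.059 with an estimated correlation). With both the block and an estimated correlation, immediate early genes were called in both conditions. Progenitor markers were higher with 2 of 11 called in both (3 and 4 adjusted over the list alone). Their adjusted p was 0.0173 and 0.0428 (adjusted p = 0.093 and 0.118 with an estimated correlation), and both calls were lost with the block (0.0623 and 0.0919). The T cell list was called with IL-4, with CD3G and CD3D higher (3 adjusted over the list alone). Its adjusted p was 0.00983 (adjusted p = 0.059 with an estimated correlation). In the blocked test alone, interferon-stimulated genes were lower without (0.607, blocked 0.0445) and with IL-4 (0.239, blocked 0.00073). With the block and an estimated correlation both calls were lost (adjusted p = 0.885 and 0.684), and the second also without the 2 libraries with the most genes detected (blocked 0.0846). Macrophage identity genes were lower without IL-4 (0.29, blocked 0.0187) and NF-kappaB and inflammatory cytokine genes higher with IL-4 (0.172, blocked 0.0278) in that test alone, and these calls were lost as well (adjusted p = 0.241 and 0.641).

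The counts for NIC1 against DNMAML also moved with single libraries. Without IL-4 the count was 100 and 114 without NIC1 replicates 1 and 2, and 77 and 95 without DNMAML replicates 1 and 3. With IL-4 it was 109, 109 and 128 without NIC1 replicates 1, 2 and 3, and 70 and 79 without DNMAML replicates 1 and 3. With the 2 libraries with the most genes detected left out it was 179 without and 71 with IL-4, and fits of only the 2 groups compared called 60 and 54. Of 29 named and called genes in each condition, 14 kept their call in every leave-out without IL-4. With IL-4 the 8 that did were HES4, DTX1, CD3G, CD3D, CD1C, PPP1R3A, MMP2 and PRTN3.

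**Figure D4:**
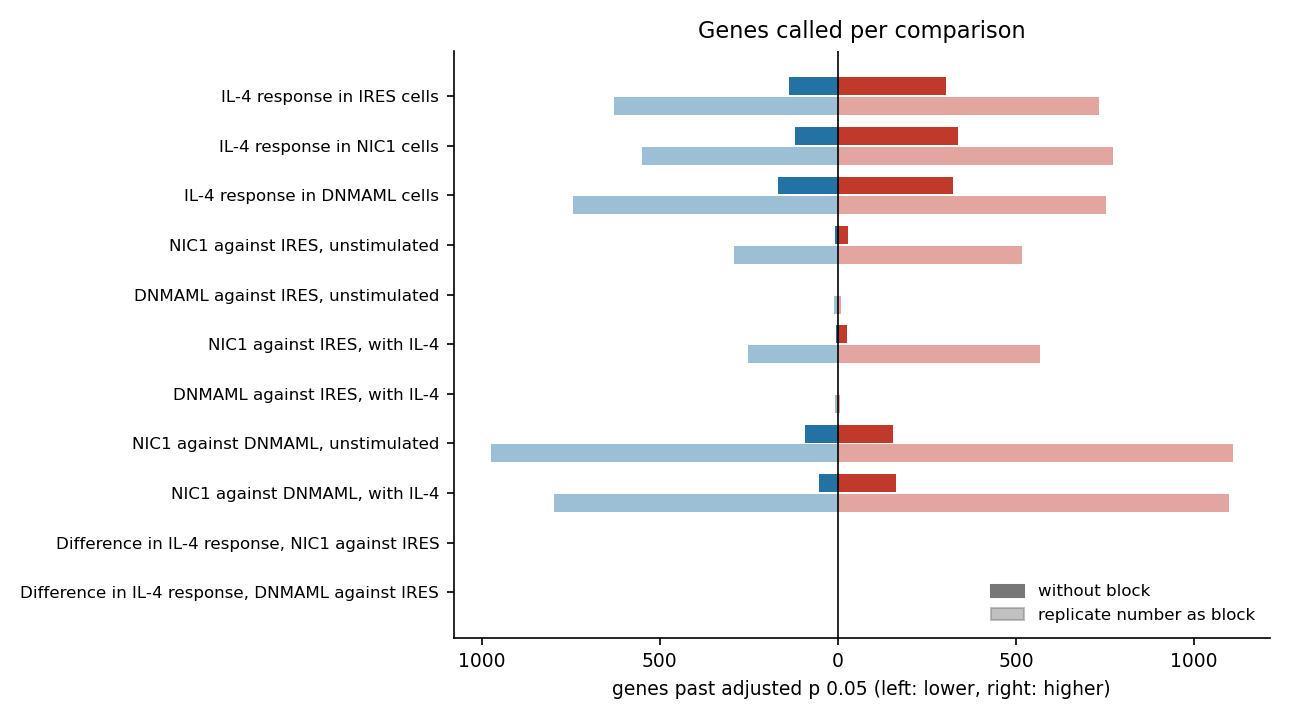
Number of genes past an adjusted p of 0.05 in each of the 11 comparisons, lower genes to the left and higher genes to the right of 0, dark for the model of group means and pale for the model with the experiment number as a block. NIC1 against DNMAML without IL-4 went from 248 to 2082 genes and DNMAML against IRES without IL-4 from 0 to 22.

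Both constructs were compared with the same IRES libraries, which by itself makes the changes correlate. Over 20 simulations of unchanged groups against these libraries, which kept the differences between experiment numbers, the correlation of log2 changes averaged 0.498 without IL-4 (0.443 to 0.554) and 0.501 with it (0.457 to 0.548). The changes measured in NIC1 and DNMAML cells correlated at -0.000717 and -0.0288. Their covariance was -5.08e-05 against a simulated 0.0227 without IL-4, a difference of -0.0227. With IL-4 it was -0.00199 against 0.0212, a difference of -0.0232. With the block, 9 genes were called higher in NIC1 and lower in DNMAML without IL-4 and 4 the other way, against 0.413 and 0.194 for independent lists. With IL-4 these were 6 and 4, against 0.302 and 0.1, and 0 genes were called in the same direction in either condition. The 3 IRES libraries of a condition are too few to be parted into sets of at least 2. In the simulations 66.7% of genes changed with the same sign in both, against 49.3% measured without and 48.9% with IL-4.

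With all libraries, 5 of the remaining lists were called as sets in no contrast, with or without the block. They were cholesterol synthesis (21 tested members, lowest camera adjusted p over the 11 contrasts 0.371), cholesterol efflux and fatty acid (20, 0.203), glycolysis (25, 0.257), apoptosis (21, 0.113) and fibroblast and epithelial genes (9, 0.399). Apoptosis regulators were called higher in NIC1 than in IRES cells without IL-4 when the 2 libraries with the most genes detected were left out (adjusted p = 0.037, blocked 0.197; adjusted p = 0.471 with an estimated correlation). With all libraries, interferon-stimulated (36, 0.182), macrophage identity (38, 0.182), unfolded protein response (22, 0.158) and mitochondrially encoded genes (13, 0.063) were called only with the block, and in no contrast with the block and an estimated correlation. Further blocked calls in the IL-4 response were lower cell cycle genes in IRES (0.243, blocked 0.0179), NIC1 (0.11, blocked 0.0019) and DNMAML cells (0.185, blocked 0.0268). They were lost with the block and an estimated correlation (adjusted p = 0.844, 0.876 and 0.794). The call in DNMAML cells was also lost without the 2 libraries with the most genes detected (blocked 0.61). In IRES cells, Notch pathway components (0.106, blocked 0.0461) and progenitor markers (0.0868, blocked 0.0461) were lower in the blocked test, with adjusted p = 0.374 for both with the block and an estimated correlation. Unfolded protein response genes were higher in it in NIC1 than in IRES cells without IL-4 (0.158, blocked 0.0147; adjusted p = 0.566 with the block and an estimated correlation). For the difference in IL-4 response of NIC1 from IRES, interferon-stimulated genes were called lower in the blocked test with all libraries (0.926, blocked 0.00938; adjusted p = 0.977 with the block and an estimated correlation). Mitochondrially encoded genes were called lower in the blocked test in the IL-4 response of DNMAML cells (0.0881, blocked 0.00724) and in its difference from IRES (0.684, blocked 0.00801), with adjusted p = 0.708 and 0.91 with the block and an estimated correlation. Without the 2 libraries with the most genes detected, the first call was lost (blocked 0.771) and the second turned to higher (blocked 0.000438).

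Leaving out the 2 libraries with the most genes detected also added calls in the test without the block. In the IL-4 response of IRES cells, interferon-stimulated genes (adjusted p = 0.0356) and unfolded protein response genes (0.0237) were higher (adjusted p = 0.972 for both with an estimated correlation). In NIC1 against IRES without IL-4, unfolded protein response genes (0.00249, blocked 0.00456) and interferon-stimulated genes (0.0439, blocked 0.382) were higher (adjusted p = 0.706 and 0.85 with an estimated correlation). For the difference in IL-4 response of NIC1 from IRES, interferon-stimulated genes were lower with and without the block (0.00934, blocked 0.00503; adjusted p = 0.987 with an estimated correlation). With the block in addition, mitochondrially encoded genes were lower in the IL-4 response of IRES cells (0.107, blocked 0.0352) and in NIC1 than in DNMAML cells with IL-4 (0.0817, blocked 0.0458), with adjusted p = 0.787 and 0.702 with the block and an estimated correlation.

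B cell markers and erythroid and megakaryocyte markers had 3 and 2 tested members, too few for a set test. No B cell marker was called, and TAL1 of the latter list rose with IL-4 by 2.57 ± 0.217 in NIC1 and 2.37 ± 0.205 in DNMAML cells.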

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

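All tests in this part were chosen after the result was seen. Among the genes too low to be tested, DNMAML with IL-4 replicate 3 had counts in 10288, against 6081 to 6530 in the 3 IRES libraries with IL-4. IRES unstimulated replicate 3 had counts in 8158, and the other 16 libraries in 6046 to 6530.

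A candidate explanation is a low level of reads spread evenly over the genome in these 2 libraries. Genes silent in the other 16 libraries held 6.18 reads per 100 kb in IRES unstimulated replicate 3 and 11.3 in DNMAML with IL-4 replicate 3, against 0.891 to 1.26 in the others, and scaled to the genome this came to 0.839 and 0.747 of their excess of reads in no gene. Deeper sequencing is argued against, since 23143 and 24327 genes had a count after thinning to the smallest library total, against at most 21318 in the others. RNA of another cell type is argued against as well, since the 10 leading silent genes held 2.39% and 1.85% of the reads in such genes, against 5.34% to 7.58% held by the 10 leading genes of a whole library. The source of such reads stays open, and no other biological explanation was tested, since the libraries belong to different groups.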

How the results depend on the processing

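The omission of the 2 libraries with the most genes detected, with or without the block or an estimated correlation, the block for each construct and number, and camera with both the block and an estimated correlation were chosen after the data were seen. Of 407 named comparisons of a gene, none changed sign while called in any setting. DESeq2 size factors kept 406 on their side of the threshold, the DESeq2 Wald test 382, no filter 376, the replicate block 295 with 112 newly called, and the omission of 2 libraries 347. The stricter filter kept 352 of 355 and fits of only the groups compared 310 of 398. The block for each construct and number kept 149 of 199 and newly called 49. Over 2610 comparisons without 1 library, 2256 stayed, 342 lost their call and 12 gained one. Total counts per library lay between 12410668 and 15099788, so depth differed little between groups, and genes too low to pass the filter were not tested. The counts of the remaining alternatives stayed within 1.5 times of those reported. Below, the added size minimum of the 2-fold setting lowers counts by construction. The leave-outs, the omission of 2 libraries and the smaller fits hold fewer libraries, but counts did not follow the number of libraries alone. Leave-outs of 1 library gave between 0 and 26 genes for NIC1 against IRES without IL-4. For these and the other settings and for the correlations the cause was not tested.

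With the replicate block, which removes the spread between experiment numbers, the IL-4 response had 1360 genes in IRES, 1323 in NIC1 and 1496 in DNMAML cells. NIC1 against IRES had 808 without and 818 with IL-4, DNMAML against IRES 22 and 14, and NIC1 against DNMAML 2082 and 1893. These counts between constructs may be too high, since the block treats libraries of one construct and number as independent. All 9 such pairs correlated above the value that the fit gives unrelated libraries, as did 12 of 36 pairs of one number and different constructs. The overlap of the 3 IL-4 responses had 899 genes, and 53 lists were called in place of 35, with 4 of the 35 lost. The correlation of NIC1 and DNMAML changes without IL-4 went from -0.000717 to 0.000758. No named gene lost its call with the block. Beside the 112 newly called, of which only those described are given with their values, and the counts and lists given with the results, it changed no other call. With a block for each construct and number, the IL-4 responses had 2256, 2157 and 2560 genes, and the difference between the responses of NIC1 and DNMAML cells, a comparison added after the data were seen, had 13 in place of 0.

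Without the 2 libraries with the most genes detected, the IL-4 response had 286 genes in IRES and 296 in DNMAML cells, NIC1 against IRES 0 without IL-4 (810 at an unadjusted p under 0.05) and 11 with it, and NIC1 against DNMAML with IL-4 71. The correlation of NIC1 and DNMAML changes was 0.182 without and 0.0632 with IL-4. Of the 35 lists called, 33 were called again, among 45. The other 12, given with the results, were lost with an estimated correlation (adjusted p of 0.471 or more). With it 11 lists were called, and 8 with the replicate block as well, all higher and among the 35. Mitochondrially encoded genes, lower with all libraries in the blocked test of DNMAML against IRES with IL-4 (0.00288) and of the difference in IL-4 response (0.00801), were higher in both (0.0144 and 0.00144, blocked 0.000977 and 0.000438). With the replicate block in addition, the IL-4 responses had 997, 1296 and 1018 genes and their overlap 707. NIC1 against IRES then had 562 and 745, DNMAML against IRES 2 and 6, NIC1 against DNMAML 1970 and 1255, and 54 lists were called. The correlations were 0.176 and 0.00476.

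With only the groups compared in the fit, the IL-4 response had 191 genes in IRES and 259 in DNMAML cells, NIC1 against IRES 0 and 0 (729 and 782 at an unadjusted p under 0.05), and NIC1 against DNMAML 60 and 54. A 2-fold minimum left 186, 189 and 179 genes for the IL-4 responses, 12 and 10 for NIC1 against IRES and 100 and 88 for NIC1 against DNMAML. The DESeq2 Wald test called 91 and 108 for NIC1 against IRES, 2 and 1 for DNMAML against IRES and 476 and 410 for NIC1 against DNMAML. Without a filter, NIC1 against IRES had 77 and 73 and DNMAML against IRES 2 and 1. With an estimated correlation 13 lists were called, and 12 with the replicate block as well, all of them higher. The 12 called with both were Notch targets and immediate early genes in NIC1 against IRES and against DNMAML in both conditions, and IL-4 and STAT6 response genes in the 3 IL-4 responses and in NIC1 against IRES without IL-4. Called with an estimated correlation but not with both were IL-4 receptor signalling components in the 3 IL-4 responses and the T cell list in NIC1 against IRES without IL-4. So were IL-4 and STAT6 response genes in NIC1 against IRES with IL-4 and against DNMAML in both conditions. The fry test asks whether the genes of a list move one way, without comparing them with other genes. It called 28 lists, 23 of the 35 among them. The 12 lost were Notch targets, NF-kappaB and inflammatory cytokine genes and cell cycle genes in NIC1 against IRES in both conditions, and in DNMAML against IRES cell cycle genes and progenitor markers in both, NF-kappaB and inflammatory cytokine genes without IL-4 and MHC class II genes with it.

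Leaving out 1 library at a time gave 314 to 394 genes for the IL-4 response in IRES, 313 to 388 in NIC1 and 301 to 424 in DNMAML cells. NIC1 against IRES ranged from 0 to 26 without and 0 to 18 with IL-4, NIC1 against DNMAML from 77 to 215 and from 70 to 209, and DNMAML against IRES and the differences in IL-4 response stayed at 0.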

Other observations

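The tests in this part were chosen after the result was seen, except 3: the share of opposed changes without the 2 libraries with the most genes detected, the share across conditions, and the direction of IL-4 response genes in NIC1 cells. The opposed direction had been noticed in the blocked lists before the first 2 of these were run.

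The libraries of experiment 2 differed from those of experiments 1 and 3 in named groups of genes, in all 3 constructs and both conditions. Interferon-stimulated genes were lower in experiment 2 by a mean log2 difference of -1.92 ± 0.491 (SD over 6 groups), with 0 of 36 members higher. MHC class II genes (-0.952 ± 0.289), unfolded protein response genes (-0.593 ± 0.0933), cell cycle genes (-0.521 ± 0.226) and macrophage identity genes (-0.438 ± 0.0628) were lower too. Mitochondrially encoded genes were higher by 1.01 ± 0.311, with 13 of 13 members higher, NF-kappaB and inflammatory cytokine genes by 0.63 ± 0.112 (24 of 30) and Notch targets by 0.369 ± 0.0835 (14 of 16). These values carry no test, and the labels say nothing of how the experiments differed.

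With the replicate block, 29 genes were called in DNMAML against IRES in at least 1 condition, and 7 in both: ACP5, CD36, FOS, MAF, MAML1, MMP2 and NOTCH1. Those described here were chosen after their values were seen. Without the 2 libraries with the most genes detected, MAF (adjusted p = 0.043) and MAML1 alone were called without IL-4, and 6 genes with it, among them MAF (0.0191), ACP5, MMP2 and MMP7. CD36, FOS, NOTCH1 and IL13RA1 were then called in neither condition. The transcription factor gene MAF (16:79585843 to 79600714) was lower in DNMAML cells by -1.22 ± 0.248 (edgeR adjusted p = 0.856, blocked 0.00111) and higher in NIC1 cells by 1.09 ± 0.233 (adjusted p = 0.0754, blocked 1.86e-05). The scavenger receptor gene CD36 (7:80369575 to 80679277) was at -0.76 ± 0.317 in DNMAML (blocked 0.0398) and 0.85 ± 0.308 in NIC1 cells (blocked 0.000306). With IL-4, the matrix metalloproteinase gene MMP7 (11:102520508 to 102530753) was at -0.94 ± 0.485 in DNMAML (blocked 0.0054) and 1.29 ± 0.475 in NIC1 cells (blocked 6.99e-06). MMP2 (16:55389700 to 55506691) went the other way, at 0.40 ± 0.142 in DNMAML (blocked 0.03) and -0.87 ± 0.145 in NIC1 cells. The phosphatase gene ACP5 (19:11574660 to 11579008) was lower in DNMAML cells (-0.83 ± 0.144 with IL-4, blocked 0.000637) and at 0.10 ± 0.141 in NIC1 cells (blocked 0.715). The IL-13 receptor subunit gene IL13RA1 was at 0.36 ± 0.277 in DNMAML (blocked 0.0253) and -0.46 ± 0.278 in NIC1 cells (blocked 0.000286) with IL-4. These changes and standard errors are from the model without the block. In that model none of these changes in DNMAML cells was called, and among those in NIC1 cells only that of MMP2 was (edgeR adjusted p = 0.026).

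The IL-4 responses of NIC1 and DNMAML cells were also set against each other, a comparison and a model chosen after the data were seen. With a block for each construct and number, 13 genes differed, 11 with a higher value in NIC1, with 1304 genes at an unadjusted p under 0.05 and 752 expected by chance. The other models called 0: the group means by edgeR, with 214 at an unadjusted p under 0.05, the block for the experiment number alone, with 610, and the DESeq2 Wald test, with 154. Beyond group and number, libraries of one construct and number correlated across genes at r = -0.123 to 0.173 over 9 pairs (median -0.0414). Removing group and number by itself gives unrelated libraries of one number a correlation of -0.2, which all 9 pairs exceeded, as did 12 of 36 pairs of different constructs (-0.415 to -0.0529). Libraries of one construct and number were thus closer to each other than other libraries of one number, but the labels do not state that they form pairs. The 13 calls rest on assuming it. The transglutaminase subunit gene F13A1 (6:6144085 to 6321013) rose by 1.06 ± 0.071 in NIC1, 0.69 ± 0.069 in IRES and 0.34 ± 0.068 in DNMAML cells (difference 0.73 ± 0.099, adjusted p = 0.00117, and 0.55 with the block for the number alone). It was past the threshold without any 1 of the NIC1 or DNMAML pairs, with an adjusted p of at most 0.0371. The count was 4, 30 and 2 without NIC1 numbers 1, 2 and 3, and 1 and 126 without DNMAML numbers 1 and 2. In data simulated with planted changes of up to 5-fold, 17 calls of this comparison were false. They made up 9.71% of its calls there, above the threshold of 0.05. A share reached beside many planted changes does not carry over to the 13 measured calls, which are fewer than those 17. How many of the 13 are false was therefore not estimated. The labels also do not state that libraries of one construct and number came from one culture.

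CD3G and CD3D, neighbours on chromosome 11, were both higher in NIC1 cells, CD3D (118338954 to 118342744) by 26.9 CPM without IL-4. T cells among the sorted cells are argued against, since the 11 other list members below 10 CPM had a median rise of -0.00063 CPM and a highest rise of 0.276. TRAC, at 89.2 CPM in IRES and 108 in NIC1 cells, was left out of that test because its baseline would hide a small share. More copies of the region are argued against by a median log2 change of 0.149 over the 10 other tested genes within 200 kb, although MPZL2 among them was at 1.51 ± 0.316 (adjusted p = 0.069, blocked 0.00363). That Notch activity sets the level stays a hypothesis that these data leave open, because CD3D in DNMAML against IRES was at -1.19 ± 0.594 (adjusted p = 1, blocked 0.387).

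Genes called for NIC1 tended to lie on the other side of 0 in DNMAML cells. Of the lists, cell cycle genes went the same way instead, lower against IRES in both constructs and conditions, with camera adjusted p of 0.00286 and 0.00015 in NIC1 and 8.92e-06 and 4.13e-06 in DNMAML cells (adjusted p = 0.834, 0.671, 0.938 and 0.856 with an estimated correlation). NF-kappaB and inflammatory cytokine genes were higher in both without IL-4 (6.48e-05 and 0.0139; adjusted p = 0.432 and 0.938 with an estimated correlation). Both constructs were compared with the same IRES libraries, which by itself gave 66.7% of genes the same sign in the simulations. These lists could therefore go the same way without an effect of either construct. For the opposed direction of single genes, the shared IRES libraries are argued against as the cause, since they push changes the same way. The 20 simulated correlations were at least 0.443, against the observed -0.000717 and -0.0288, although unrelated changes would lower a correlation too. Across conditions that share no library, the changes correlated over genes at r = -0.2 and -0.237, and 75.9% of the 808 genes called with the block for NIC1 without IL-4 lay on the other side in DNMAML with IL-4, and 74.6% of 818 in the reverse pairing. The 2 libraries with the most genes detected are argued against as the whole cause, since 71.4% of 745 lay on the other side with both left out, although the correlations within a condition then became 0.182 and 0.0632. The pattern over single genes is consistent with opposed changes of Notch activity, a hypothesis found and tested in the same libraries.

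Whether NIC1 moves unstimulated cells in the direction of IL-4 was tested on the 493 genes called in the IL-4 response of DNMAML cells, which share no library with NIC1 against IRES without IL-4. Of these, 55.2% moved the same way, between the 50% and 60% set for the test, and 52.6% of 1496 did with the block. Without the 2 libraries with the most genes detected, 1 of which is in each of these comparisons, it was 50.7% of 296, and 48.6% of 1018 with the block. Log2 changes of the 493 genes correlated at r = -0.00477. No setting reached 60% and only the last lay under 50%, so the question stays open. The fixed list of IL-4 and STAT6 response genes was called higher as a set in NIC1 against IRES without IL-4, as given above. CD1C was its only member called over all genes there.

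Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. In the IL-4 responses the real split called 441, 458 and 493 genes and the highest other split 0 in each, so that 1 of 10 splits reached the real count. In NIC1 against IRES (35 and 30 genes) and NIC1 against DNMAML (248 and 216) the highest other split called 0 as well. In DNMAML against IRES all 10 splits, the real one included, called 0. With the replicate block, 4 of the 10 splits part all 3 pairs, the real one among them, and the other 3 called 0 in each comparison, while 6 part 1 pair. For the 13 genes above, the 6 NIC1 and DNMAML pairs gave 10 splits with a highest other count of 0. For the differences in IL-4 response from IRES, 25 of 200 splits were drawn. The real count was 0, which each of the 25 reaches whatever the data, so they say nothing of chance. The highest other split called 2 genes for NIC1 and 503 for DNMAML. The split with 503 set the libraries of experiment 2 apart, both as DNMAML without IL-4 and both as IRES with it, and called 0 with the block, so it followed the experiment number. The split with 2 parted them in the reverse way and called 155 with the block.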
